A study of Homo sapiens with 5 samples.

How the data were processed

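Per the labels, RNA was extracted from MDA-MB-231 cells with TRIzol, made into Illumina libraries and sequenced on a NovaSeq instrument. There were 5 samples in 5 groups, 1 library per group: WT, TAZ-KO, TAZ-KO with Flag-TAZ, TAZ-KO with Flag-TAZ-deltaCC, and YAP-KO, and each column of the deposited tables was matched to 1 sample. The submitters' processing notes name STAR 2.5, HTSeq 0.6.1, edgeR 3.16.5 and the genome build hg38, without saying what each did. The annotation, the strand setting, the RNA selection and any filter are not given in the sources used here. The deposited count table holds raw read counts per gene, whole numbers without normalization, for 58676 genes. The deposited FPKM table holds FPKM, values per kilobase of gene length and scaled to the library's total count, computed by the authors: each of 114270 non-zero values was checked to equal the count rescaled by the given gene length and the library's total count, within a relative tolerance of 1e-06.

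Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3) computed from all 5 libraries (0.981 in WT, 1.02 in TAZ-KO, 0.973 in Flag-TAZ, 0.964 in deltaCC and 1.06 in YAP-KO) and expressed as CPM, counts scaled to a common library size. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Between 13635 and 13892 genes reached 1 CPM in a library, and 15760 did in at least 1. A floor of 3 counts corresponds to 0.150 CPM in WT, 0.142 CPM in TAZ-KO, 0.176 CPM in Flag-TAZ, 0.133 CPM in deltaCC and 0.134 CPM in YAP-KO. The 10 most abundant genes held between 5.88% and 7.27% of the counts, and mitochondrially encoded genes between 3.52% in WT and 5.11% in YAP-KO.

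With 1 library per group there are no residual degrees of freedom, so no test, p-value or standard error was computed and no library was left out. The 5 comparisons were TAZ-KO against WT, YAP-KO against WT, Flag-TAZ against TAZ-KO, deltaCC against TAZ-KO and Flag-TAZ against deltaCC. The log2 ratio is that of the CPM of the first to that of the second library after adding 0.5 CPM to each. By the size rule a gene is higher or lower when it has at least 1 CPM in at least 1 of the compared libraries, an absolute log2 ratio of at least 1, and a 95% counting interval of the ratio (exact Clopper-Pearson, conditional on the sum of both counts) that excludes equality. The interval is that of the ratio without the added 0.5 CPM, so for genes with few counts the log2 ratio can lie outside it. Intervals of single CPM values are exact Poisson intervals at the same level. A gene with 0 counts in a library is given a bound, computed with 3 counts in that library.

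Before the data were examined, 33 gene lists were fixed, and 784 of their entries matched the table by current or older symbol, while 1 (SOD2) matched more than 1 line and was left out. The lists are the YAP/TAZ signature; Hippo pathway components; AP-1 and related factors; DNA replication and G1/S; G2/M and mitosis; mesenchymal markers; epithelial markers; collagens and matrix proteins; integrins; actin cytoskeleton and SRF targets. Others are EGFR-family ligands and receptors, NF-kB and inflammatory cytokines, interferon response, HLA and antigen presentation, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and ATF4 response, p53 targets, TGF-beta and SMAD targets, and lung and bone metastasis genes of this line. The last are cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, heat shock genes, immediate early genes, MYC targets in ribosome biogenesis and replication-dependent histones, with markers of luminal breast, basal mammary epithelial, HEK293, blood and endothelial cells. Results for 1 further list and for some single genes are not reported here. A list is described by the median log2 ratio of its members with at least 1 CPM in at least 1 of the 5 libraries, and by the percentile of this median among 10000 random lists matched member by member on mean log2 CPM in 20 bins. A list stands apart at a percentile of at most 2.5 or at least 97.5. The percentile describes these libraries and is not a p-value, since members vary together.

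The rule for named genes was also fixed then. It takes WWTR1 and YAP1, the 8 protein-coding genes with the highest and the 8 with the lowest log2 ratio per comparison among those called with at least 10 CPM in the higher library, any signature member, up to 4 members of each other list with the largest absolute log2 ratio, and the 8 TAZ-dependent genes with the largest loss and at least 10 CPM in WT. TAZ-dependent genes are those lower in TAZ-KO than in WT, and the share recovered is the log2 ratio to TAZ-KO in percent of the log2 ratio of WT to TAZ-KO. Lists of 14 erythroid and 14 white blood cell genes were added after the counts of HBB were seen.

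Transcript GC content and length were taken from the longest GENCODE release 29 transcript of each gene on GRCh38, and had a value for all 15760 genes. For the GC correction, a lowess trend (span 0.2, 2 iterations) of the log2 ratio on GC content was removed. The alternatives fixed together with the gene lists were median-of-ratios, upper-quartile and total-count scaling, no filter and a minimum of 5 CPM, 0.1 and 2 CPM added before the logarithm, thresholds of 1.5-fold and 4-fold, protein-coding genes alone, and the deposited FPKM with 0.1 or 1 added. With the FPKM, a call kept the minimum of 1 CPM and the log2 threshold but did not use the counting interval. GC correction, GC and length correction, scaling without the YAP-KO library, and a minimum of 5 or 10 CPM in WT or TAZ-KO for the TAZ-dependent genes were added after seeing the data. Libraries without any difference were simulated from the pooled counts with assumed coefficients of variation of 0, 0.1 and 0.2 between libraries. The size rule was tested on simulated data with planted changes in TAZ-KO against WT: with counting noise alone it recovered 22 of 50 genes changed 2-fold and 50 of 50 changed 3-fold and called 2 unchanged genes. At an assumed coefficient of variation of 0.2 it called 236 unchanged genes, and 53.6% of the 95% counting intervals held the true ratio.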

Results

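RNA was sequenced from 5 libraries of MDA-MB-231 cells, a human triple-negative breast cancer line with mesenchymal features, with 1 library in each of 5 groups. The groups were unmodified cells (WT), TAZ knockout cells (TAZ-KO), TAZ knockout cells carrying Flag-tagged TAZ (here the Flag-TAZ library), TAZ knockout cells carrying Flag-tagged TAZ without its coiled coil (the deltaCC library), and YAP knockout cells (YAP-KO). TAZ, encoded by WWTR1, and YAP are related coactivators that bind TEAD transcription factors and are restrained by the Hippo pathway. The series asks how phase separation of TAZ gathers the transcription machinery, and the libraries allow the transcripts that differ without TAZ to be compared with those that return with either form of it. Total gene counts were 20321175 in WT, 20678837 in TAZ-KO, 17516119 in Flag-TAZ, 23462091 in deltaCC and 21072801 in YAP-KO. No group had a replicate, so no difference could be held against the spread between replicates. Every value below compares these libraries and not conditions, and intervals and floors cover counting error only. Across 15760 genes the Flag-TAZ and deltaCC libraries were the most alike (Pearson r of log2 CPM across genes 0.988), while YAP-KO had r between 0.907 and 0.928 with the other libraries. Genes are not independent replicates, so these correlations describe the libraries and carry no test.

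The transcript of WWTR1 (ENSG00000018408, GRCh38 chromosome 3, 149517235 to 149736714, minus strand) was not lower in the library labelled TAZ-KO. It stood at 117 CPM in WT (95% counting interval 112 to 122), 169 CPM in TAZ-KO (163 to 174) and 172 CPM in YAP-KO (166 to 177). In Flag-TAZ it stood at 1015 CPM, 8.70-fold the WT level, and in deltaCC at 679 CPM, 5.82-fold the WT level. YAP1 (ENSG00000137693, chromosome 11, 102110461 to 102233423, plus strand) stood at 106 CPM in YAP-KO (102 to 110), 0.503 of its level in WT, and between 208 and 227 CPM in the other libraries. Gene counts show neither small edits of a coding sequence nor the deletion of the coiled coil, so the knockouts and the deltaCC form are taken from the labels.

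**Figure D1:**
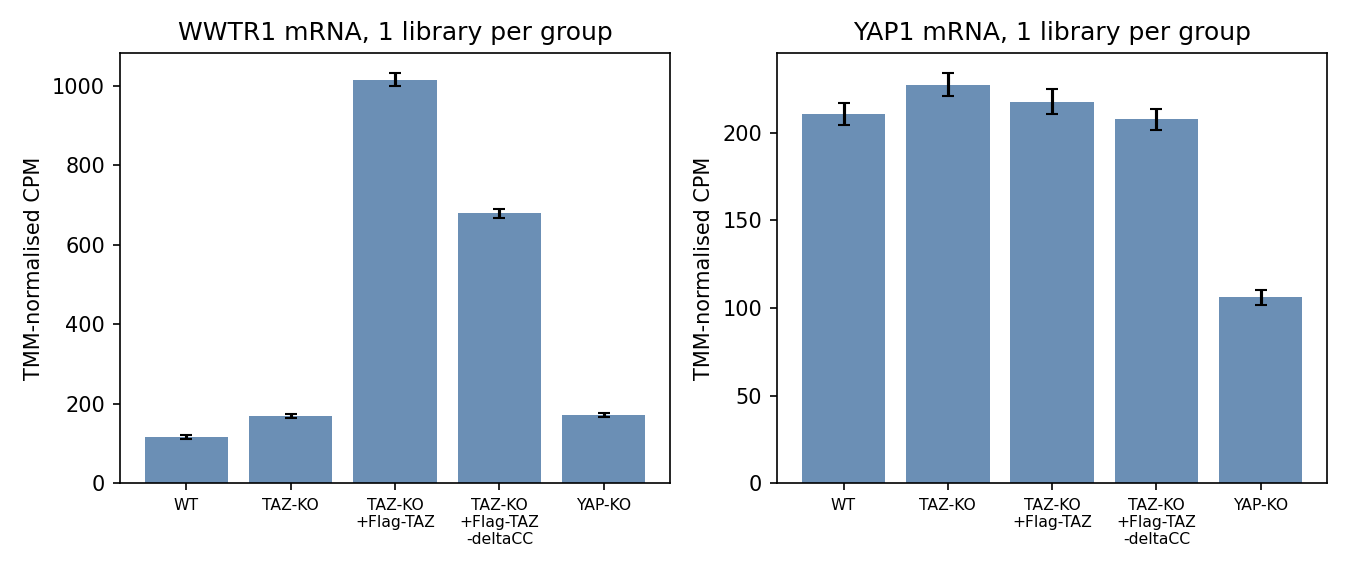
Normalised expression of WWTR1 and YAP1 (TMM-normalised CPM) in each of the 5 libraries, with 95% counting intervals as bars. WWTR1 is 8.70-fold the WT level in Flag-TAZ and 5.82-fold in deltaCC, and YAP1 in YAP-KO is 0.503 of the WT level.

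The comparison of TAZ-KO with WT addresses which transcripts differ without TAZ. Transcripts far lower in TAZ-KO included THBS2 (the matrix glycoprotein thrombospondin 2), HAS2 (a hyaluronan synthase) and TRPV4 (a calcium channel), and the well-known YAP and TAZ targets ANKRD1 and CTGF were lower. The interferon response, epithelial markers and replication-dependent histones were higher as lists. By the size rule 930 genes were higher and 793 lower among 14779 tested, most of them at low expression: with a minimum of 5 CPM, 254 were higher and 234 lower. THBS2 (ENSG00000186340, chromosome 6, 169215780 to 169254044) was at 116 CPM in WT and 6.14 CPM in TAZ-KO, a log2 ratio of -4.13 (ratio interval -4.50 to -3.98). HAS2 was at 14.7 CPM and 0.472 CPM, and TRPV4, with 0 counts in TAZ-KO, was at least 76.8-fold lower, taking 3 counts per library as the floor. The transcription factor KLF9 was at 45.0 CPM in WT and 5.29 CPM in TAZ-KO, and SERPINA1, the protease inhibitor alpha-1-antitrypsin, at 51.8 CPM and 7.84 CPM. CRIP2, a LIM-domain protein, was at 16.4 CPM and 1.23 CPM, SPATA5L1 at 10.9 CPM and 1.84 CPM, and the cancer-testis gene PAGE2, which has close copies, at 11.7 CPM and 0.189 CPM. Among the higher genes, PTGFRN, a tetraspanin partner (ENSG00000134247, chromosome 1, 116910057 to 116990358), was at 0.251 CPM in WT and 34.0 CPM in TAZ-KO. The protocadherin PCDH7 was at 0.150 CPM and 19.3 CPM, with 3 counts in WT and a log2 ratio interval of 5.44 to 9.29. Unlike PAGE2, the cancer-testis gene MAGEC1 was higher, at 2.86 CPM in WT and 58.5 CPM in TAZ-KO, as were SPANXB1 at 6.57 CPM and 93.3 CPM and SSX1 at 0.401 CPM and 15.4 CPM. SPANXB1 and SSX1 belong to families of near-identical copies, so their counts are uncertain. The sphingosine-1-phosphate receptor S1PR3 was at 1.25 CPM and 12.05 CPM, and EMB, encoding embigin, at 0.953 CPM and 20.1 CPM. Of the 8 highest and the 8 lowest genes, 7 and 7 had the same call against WT in both Flag-TAZ and deltaCC. MAGEC1, for example, was at 57.7 CPM in Flag-TAZ and 57.1 CPM in deltaCC. A kept call can go with a partial return, as for HAS2, at 6.10 CPM in Flag-TAZ and 3.41 CPM in deltaCC. These are the most extreme genes. Of all 1723 called genes, 254 (14.7%) kept their call in both libraries.

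In the YAP/TAZ signature, 22 genes taken as shared targets of both coactivators, 18 members were below 0 in TAZ-KO against WT and the median log2 ratio was -0.29, lower than in all 10000 matched random lists (percentile 0). The size rule called 2 members lower, none higher and 20 neither. ANKRD1, a muscle ankyrin-repeat protein, was at 265 CPM in WT and 101 CPM in TAZ-KO (log2 ratio -1.39, interval -1.47 to -1.32), and the matricellular factor CTGF at 381 CPM and 183 CPM (log2 ratio -1.05, interval -1.11 to -0.9998). CYR61, another matricellular target, was at 704 CPM and 549 CPM (log2 ratio -0.36), which the size rule did not call.

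Of the 33 lists, 12 stood apart in TAZ-KO against WT, the signature among them. The interferon response had a median log2 ratio of 0.28 (percentile 100), with 4 of 35 measured members higher, 1 lower and 30 not called: SAMD9 was at 6.47 CPM in WT and 47.2 CPM in TAZ-KO, and the antiviral genes RSAD2 at 0.251 CPM and 3.12 CPM and MX2 at 1.003 CPM and 3.40 CPM. Epithelial markers had a median of 0.38 (percentile 99.8) with 1 of 18 called, SPINT1, higher at 3.02 CPM against 0.752 CPM in WT. Replication-dependent histones had a median of 0.60 (percentile 99.7) with 2 of 11 called, both higher: HIST1H2AC at 15.4 CPM against 5.12 CPM and HIST1H2BJ at 4.63 CPM against 1.15 CPM. Immediate early genes had a median of 0.22 (percentile 98.9), with 3 of 23 higher and none lower, including the phosphatase gene DUSP1 at 33.4 CPM against 14.2 CPM. They no longer stood apart with 2 CPM added (percentile 91.7) or with the deposited FPKM plus 1 (92.4) or 0.1 (95.8). Among genes tied to lung and bone metastasis of this line (median 0.15, percentile 97.8), 4 of 19 were higher and 2 lower, with 10 above 0 and 9 below. The higher ones were the scaffold NEDD9 at 43.8 CPM against 16.6 CPM in WT, PTGS2 (cyclooxygenase 2) at 90.8 CPM against 36.2 CPM, KYNU at 19.8 CPM against 7.82 CPM and the collagenase MMP1 at 116 CPM against 47.9 CPM. The metastasis list no longer stood apart with 2 CPM added (percentile 96.6) or with the deposited FPKM plus 1 (71.2). The unfolded protein and ATF4 response had a median of 0.12 (percentile 98.5), with 1 of 26 higher and 2 lower: DNAJB9 was at 12.9 CPM against 5.52 CPM in WT, while PHGDH, the first enzyme of serine synthesis, was at 11.5 CPM against 45.8 CPM. Ribosomal proteins had a median of 0.036 (percentile 99.3) with 0 of 52 called. Cholesterol synthesis had a median of 0.15 (percentile 98.2, and 94.8 after GC correction), with SC5D higher at 17.5 CPM against 5.17 CPM and TM7SF2 among the lower members (log2 ratio -1.04, and -0.95 and not called after GC correction).

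Lists standing apart on the low side were collagens and matrix proteins, DNA replication and endothelial markers. Collagens and matrix proteins had a median log2 ratio of -0.24 (percentile 0.26), but 2 of the 25 were higher, COL1A1 at 80.5 CPM against 33.6 CPM in WT and the laminin LAMA4 at 9.36 CPM against 3.91 CPM, and only THBS2 was lower by the size rule. DNA replication and G1/S had a median of -0.18 (percentile 0.845) with 30 of 35 below 0, of which 2 were called lower: GINS3, of the replicative helicase, at 3.92 CPM against 9.13 CPM, and E2F8 at 9.07 CPM against 18.8 CPM (log2 ratio -1.01, and -0.94 and not called after GC correction). Endothelial markers had 5 measured members and a median of -0.75 (percentile 0.395), with the receptor ROBO4 at 28.9 CPM against 79.8 CPM. Markers of blood cells did not stand apart (median 0.52, percentile 92.1), though HBB, the beta chain of haemoglobin, was at 54.1 CPM in TAZ-KO and 15.0 CPM in WT.

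The comparison of YAP-KO with WT addresses which transcripts differ without YAP. Mitotic genes, mitochondrially encoded genes, ribosomal proteins and histones were higher as lists in YAP-KO, and the interferon response and the EGFR family were lower. Desmoplakin (DSP), filamin A, talin and non-muscle myosin were lower, in lists of epithelial markers and of actin and SRF genes that did not stand apart. The size rule called 2723 genes higher and 1653 lower among 14704 tested, the most of the 5 comparisons. This library also stood apart in base composition: the log2 ratios went down with transcript GC content (Spearman rho across 12776 genes -0.622), from a median of 1.36 in the 10% of genes with the lowest GC content to -0.58 in the 10% with the highest. With this trend removed, 1289 genes were higher and 1253 lower, so GC-corrected values are given beside the gene groups. Scaling by upper quartiles moved all YAP-KO log2 ratios against WT by -0.33 and reversed the split, to 1737 higher and 2827 lower.

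**Figure D2:**
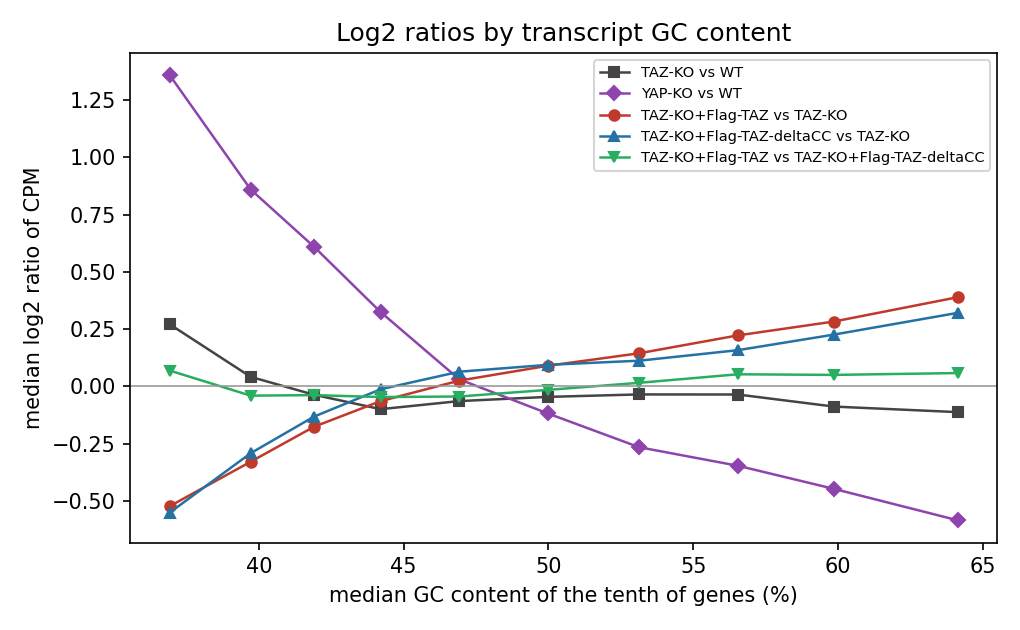
Median log2 ratio (vertical axis) in each of 10 equal groups of 12776 protein-coding genes ordered by transcript GC content in percent (horizontal axis), with 1 line for each of the 5 comparisons. YAP-KO against WT runs from 1.36 to -0.58, and Flag-TAZ and deltaCC against TAZ-KO run the other way.

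Among the genes lower in YAP-KO, the kinase gene DAPK1 was at 25.1 CPM in WT and 0.536 CPM in YAP-KO, a log2 ratio of -4.63 (-4.37 after GC correction). THBS2 was lower here too, at 4.96 CPM against 116 CPM. INHBB, a subunit of activin B, was at 0.894 CPM against 21.6 CPM, DENND2A at 0.805 CPM against 26.6 CPM, C6orf132 at 2.82 CPM against 46.8 CPM and APBA2 at 0.179 CPM against 10.98 CPM. PAGE2, with 0 counts in YAP-KO, was at least 87.1-fold lower, and HBB was at 0.179 CPM. Among the higher genes, the microtubule-associated kinase DCLK1 was at 36.4 CPM against 0.501 CPM in WT and the centrin CETN3 at 36.5 CPM against 0.702 CPM. The secretory-pathway genes TMED7 and IER3IP1 were at 127 CPM against 4.46 CPM and at 29.9 CPM against 0.602 CPM. COX7B2 and ZNF300 had 0 counts in WT and were at least 79.6-fold and 76.1-fold higher. TPT1, at 481 CPM against 15.9 CPM, and the histone HIST1H4I, at 27.8 CPM against 0.401 CPM, have near-identical copies, so their counts are uncertain. These 16 genes had the same call after GC correction, but the log2 ratios of the 8 higher genes fell. The fall was from 4.94 to 3.32 for CETN3, 4.79 to 3.56 for IER3IP1 and 4.68 to 3.51 for TMED7, and least for HIST1H4I (4.97 to 4.95).

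The YAP/TAZ signature did not stand apart in YAP-KO against WT: its median log2 ratio was -0.24 (percentile 49.96; -0.30 and percentile 25.01 after GC correction), with 2 of 22 higher, 6 lower and 14 not called. The receptor tyrosine kinase AXL was at 979 CPM against 3404 CPM in WT (log2 ratio -1.80, interval -1.82 to -1.78), NUAK2 at 4.83 CPM against 18.8 CPM, PTPN14 had a log2 ratio of -1.58 and DOCK5 -1.23. ARHGEF17 (-1.14) and LATS2 (-1.05) were called lower as measured and not after GC correction (-0.60 and -0.83). GADD45A was higher (1.21), and RBMS3 had 1.21 as measured and -0.12 after GC correction. CTGF (0.68), CYR61 (0.19) and ANKRD1 (-0.25) were not called.

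Among the gene groups of YAP-KO against WT, 10 stood apart. G2/M and mitosis had a median log2 ratio of 0.52 (percentile 100; 0.25 after GC correction), with 9 of 35 higher and 1 lower (4 and 2 after GC correction): HMMR was at 20.6 CPM against 2.66 CPM in WT and the spindle checkpoint kinase TTK at 69.6 CPM against 12.8 CPM. CENPE, a kinetochore motor, and CDK1 had log2 ratios of 2.33 and 2.25 as measured but 0.81 and 0.97 after GC correction, which the size rule does not call. Nuclear-encoded oxidative phosphorylation had a median of 0.50 (percentile 99.4; 0.57 corrected), with 10 of 42 higher and none lower (9 and 0 after GC correction), such as UQCRB at 85.8 CPM against 10.1 CPM, SDHD at 45.1 CPM against 7.47 CPM and COX7B at 73.0 CPM against 19.5 CPM. Mitochondrially encoded genes had a median of 0.73 (0.69 corrected), with 5 of 13 higher and 1 lower, MT-CO2 at 5366 CPM against 1665 CPM among them, but 2 higher and 3 lower after GC correction. Histones had a median of 1.81 (1.88 corrected), with 8 of 11 higher: HIST1H2AC was at 65.2 CPM against 5.12 CPM, HIST1H2BK at 87.8 CPM against 14.8 CPM and HIST1H1C at 68.4 CPM against 12.3 CPM. DNA replication and G1/S genes did not stand apart (median -0.011, percentile 52.0; -0.053 and percentile 52.3 after GC correction). The RNA selection is not given, so whether it affected the histone counts cannot be told. Ribosomal proteins had a median of 0.27 (percentile 100; 0.44 corrected; -0.054 with upper-quartile scaling), with 6 of 52 higher (3 after GC correction), RPL22 at 100.2 CPM against 22.9 CPM and RPS12 at 325 CPM against 121 CPM. Heat shock genes had a median of 0.65 (percentile 99.8), which did not remain after GC correction.

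The interferon response was lower as a list in YAP-KO against WT (median -0.34, percentile 0.84; -0.50 corrected), with 3 of 35 higher and 5 lower: OAS3 was at 51.3 CPM against 175 CPM, while SAMD9 was at 41.1 CPM against 6.47 CPM and IFI44 at 23.9 CPM against 3.81 CPM. Ligands and receptors of the EGFR family had a median of -0.79 (percentile 0.805; -0.62 corrected, and percentile 5.58 after GC and length correction), with 1 of 11 higher and 3 lower (0 and 3 after GC correction): epiregulin (EREG) at 6.17 CPM against 20.7 CPM, ERBB2 at 49.4 CPM against 141 CPM, and NRG2. Collagens and matrix proteins had a median of -0.71 (percentile 0.21), with 10 of 25 lower and none higher, including COL6A2 at 0.760 CPM against 16.2 CPM and COL6A1 at 48.4 CPM against 146 CPM. After GC correction the collagen median was -0.27 (percentile 22.4), with 9 lower and 1 higher, so the list no longer stood apart. Blood markers had a median of -0.71 (percentile 2.5; -0.54 with members at 0 counts set to the floor, and percentile 9.66 after GC correction). Other lists held strongly lower members without standing apart. Of the actin and SRF list (median -0.27, percentile 46.9; percentile 82.2 after GC correction), 5 of 28 were lower and 2 higher (5 and 1 after GC correction), with FLNA (log2 ratio -1.92), TLN1 (-1.78) and MYH9 (-1.61) lower. Epithelial markers had a median of -0.50 (percentile 4.35; -0.38 and percentile 7.45 after GC correction), with 5 of 18 lower and 2 higher (4 and 2 after GC correction): DSP was at 29.1 CPM against 350 CPM, KRT19 at 141 CPM against 548 CPM and KRT8 at 257 CPM against 711 CPM. Among integrins, 4 of 15 were lower (2 after GC correction), ITGA3 at 1115 CPM against 3700 CPM, and the median of -0.22 (percentile 45.6) was -0.61 (percentile 1.88) after GC correction.

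**Figure D3:**
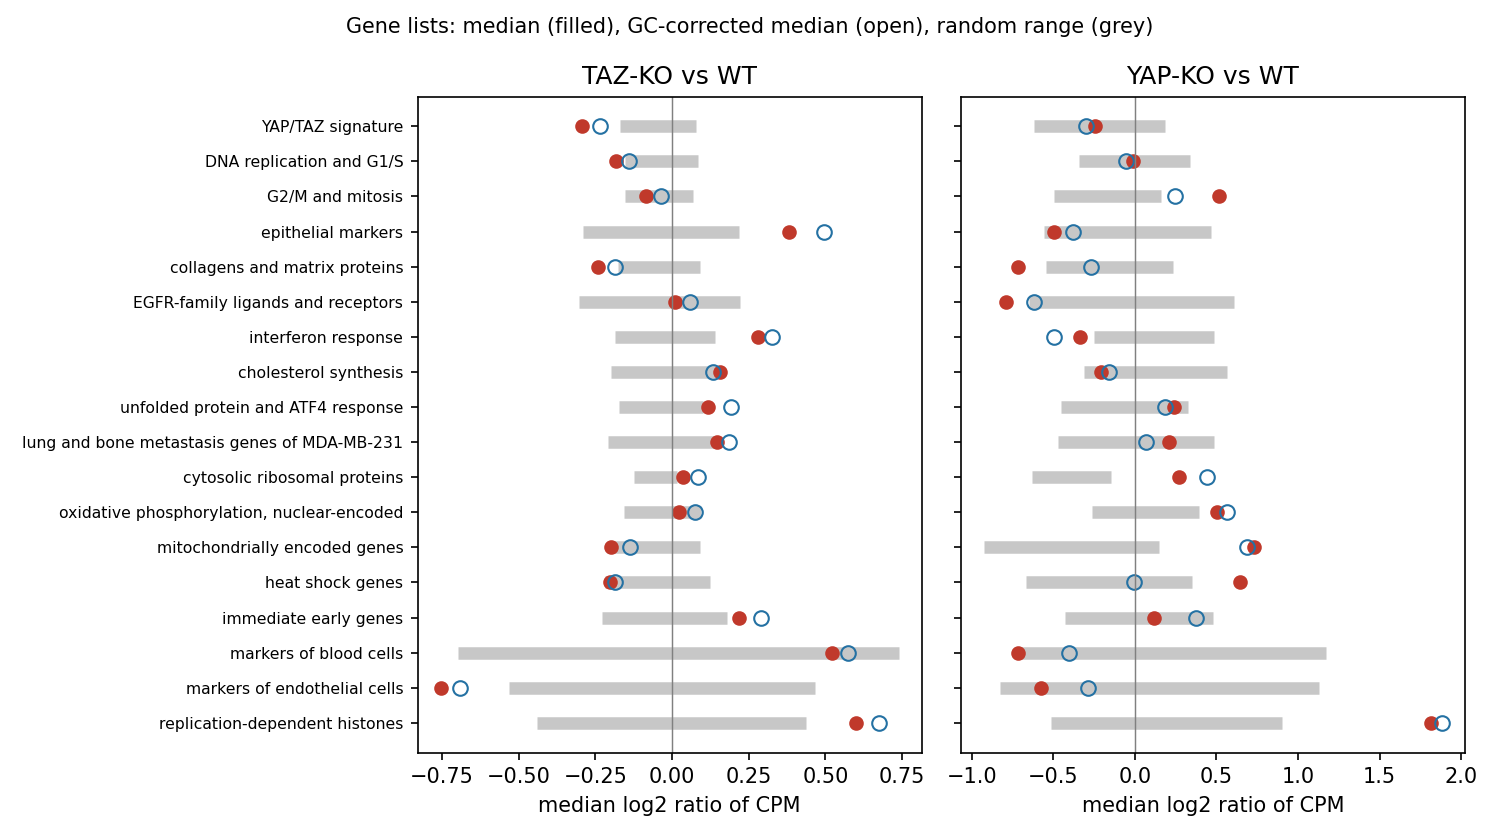
Median log2 ratio of the gene lists that stood apart in TAZ-KO against WT or in YAP-KO against WT (filled red, as measured; open blue, GC-corrected), with the range of matched random lists in grey. The interferon response lies at 0.28 in TAZ-KO and -0.34 in YAP-KO.

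The overlap of the knockouts addresses whether the same genes differ without either coactivator. Among 14112 genes tested in both, 294 were higher in both knockouts, where independent calls would give 84.3, and 206 were lower in both, where 92.9 would be given. Opposite calls numbered 33 and 65, against 59.0 and 133 under independence. After GC correction 171 were higher in both (34.2 under independence) and 157 lower in both (66.5). THBS2 and PAGE2 were among the genes lower in both, and SAMD9 among those higher in both. THBS2 was also low in Flag-TAZ (8.57 CPM) and deltaCC (10.7 CPM), against 116 CPM in WT, and PAGE2 had 0 counts in both. For THBS2 and PAGE2 it was thus WT that differed from every other library. With 1 WT library this cannot be told apart from a shared effect. SAMD9 was at 15.5 CPM in Flag-TAZ and 8.01 CPM in deltaCC, nearer its 6.47 CPM in WT. The TAZ-KO and YAP-KO comparisons share the WT library: in simulated libraries without any difference, sharing it alone gave r across genes between 0.511 and 0.550, and the measured r was 0.329 (Spearman rho 0.279). The measured covariance was 0.194 (0.121 after GC correction), against 0.0125 in simulation with counting noise alone and 0.0885 with an assumed coefficient of variation of 0.2. At 0.2 the simulations also gave 21.15 genes higher in both and 9.6 lower in both, with 245 genes called per comparison. Sharing the WT library thus lifts the overlap above independence by itself. The excess over independence therefore does not show a shared effect of the knockouts.

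The comparison of Flag-TAZ with TAZ-KO addresses which transcripts differ with full-length TAZ, whether toward the WT level or away from it. ANKRD1 was back at its WT level, CTGF and CYR61 were higher than in TAZ-KO, and ribosomal proteins were higher as a list and integrins lower. Immediate early genes, replication genes and MYC targets were higher as lists as measured, but no longer stood apart after GC and length correction. In TAZ-KO against WT the median log2 ratios had been 0.036 for ribosomal proteins, -0.16 for integrins (percentile 10.9) and 0.22 for immediate early genes. For these lists the difference in Flag-TAZ was thus not a return toward WT. The size rule called 694 genes higher and 944 lower among 14635 tested (201 and 282 with a minimum of 5 CPM, without GC correction). The log2 ratios went up with GC content (Spearman rho across genes 0.495), and 629 were higher and 781 lower after its correction. ANKRD1 was at 265 CPM against 101 CPM in TAZ-KO (log2 ratio 1.39, interval 1.32 to 1.47), NUAK2 at 21.1 CPM against 9.54 CPM (1.11, and 0.91 and not called after GC correction), and CTGF at 364 CPM against 183 CPM, which at a log2 ratio of 0.99 was not called. CYR61 was at 850.3 CPM against 549 CPM. The signature median was 0.41 (percentile 100) with 17 of 22 members above 0, 2 called higher and 20 not called. Beyond WWTR1 itself, the highest genes were the placental alkaline phosphatase ALPP at 10.97 CPM against 0.472 CPM, adrenomedullin (ADM) at 69.5 CPM against 12.9 CPM, the stress gene GADD45B at 19.9 CPM against 4.02 CPM, the activin antagonist follistatin (FST) at 39.5 CPM against 9.07 CPM and SCARF2 at 11.1 CPM against 2.98 CPM. SERF2 (12.3 CPM against 1.56 CPM) and COX6A1 (12.7 CPM against 1.94 CPM) were also higher, but overlapping or copied loci make their counts uncertain. In WT, ALPP, ADM, FST and SCARF2 were at 0.552, 12.99, 10.68 and 2.36 CPM, near their TAZ-KO levels, so their rise was not a return toward WT. GADD45B, SERF2 and COX6A1 were at 12.04, 7.17 and 3.01 CPM in WT, above TAZ-KO, and rose past the WT level. The lowest genes were MAP9, a microtubule-associated protein, at 2.17 CPM against 10.8 CPM, ORC5 of the origin recognition complex at 2.58 CPM against 12.4 CPM, PGAP1 at 2.46 CPM against 11.6 CPM, ZNF33B, GOLT1B at 6.28 CPM against 25.8 CPM, RBM27, FRA10AC1 and CASP8AP2 at 4.17 CPM against 14.5 CPM. They kept their call after GC correction with smaller log2 ratios, from -2.08 to -1.44 for MAP9, -1.96 to -1.30 for GOLT1B and -2.07 to -1.83 for ORC5.

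Of the lists in Flag-TAZ against TAZ-KO, 9 stood apart. Immediate early genes had a median log2 ratio of 0.37 (percentile 99.8; 95.4 after GC correction) with 5 of 23 higher and none lower: the zinc-finger factor EGR1 was at 65.1 CPM against 20.9 CPM, DUSP1 at 101 CPM against 33.4 CPM and NR4A1 at 4.58 CPM against 0.898 CPM. Ribosomal proteins had a median of 0.39 (percentile 100) with 46 of 52 above 0 and 2 called higher, RPL30 at 91.2 CPM against 33.5 CPM and RPS24 at 242 CPM against 114 CPM. DNA replication had a median of 0.24 (percentile 99.1; 94.1 after GC and length correction) with 27 of 35 above 0 and 2 higher, GINS3 at 10.9 CPM against 3.92 CPM and TYMS at 34.8 CPM against 15.3 CPM. MYC targets in ribosome biogenesis had a median of 0.25 (percentile 98.9; 95.7 after GC and length correction) with 0 of 28 called. TGF-beta and SMAD targets had a median of 0.26 (percentile 98.1; 44.9 after GC correction), with ID3 (not called after GC correction) and the activin subunit INHBA, at 28.1 CPM against 13.6 CPM, higher. Luminal markers had a median of 0.36 (percentile 98.4; 0.30 with members at 0 counts set to the floor) with 0 of 10 called. Integrins had a median of -0.36 (percentile 0.08), with 1 of 15 lower, ITGA1 at 26.4 CPM against 59.0 CPM, and 2 higher, but with none lower and 1 higher after GC correction. Blood markers had a median of -0.79 (percentile 2.27), with 2 of 6 lower (4 after GC correction) and HBB at 22.1 CPM against 54.1 CPM.

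The comparison of deltaCC with TAZ-KO addresses which transcripts differ with TAZ lacking the coiled coil, again toward the WT level or away from it. The signature, immediate early genes, mitochondrially encoded genes and histones were higher as lists, as were actin and SRF genes before GC correction, and ribosomal proteins and blood markers were lower. Immediate early genes and histones were already higher than WT in TAZ-KO (median log2 ratios 0.22 and 0.60), so their rise was not a return toward WT. The size rule called 572 genes higher and 873 lower among 14722 tested (560 and 641 after correction of a GC trend with rho 0.465, and 97 and 349 with a minimum of 5 CPM). The signature median was 0.23 (percentile 97.8) with 16 of 22 members above 0. NUAK2 was at 22.3 CPM against 9.54 CPM in TAZ-KO and was the member called higher. ANKRD1 was at 144 CPM against 101 CPM (log2 ratio 0.51, interval 0.43 to 0.59), CTGF at 260.4 CPM against 183 CPM (0.50) and CYR61 at 810.3 CPM against 549 CPM (0.56), none of them called. GADD45B was at 12.1 CPM against 4.02 CPM, OXCT1, an enzyme of ketone body use, at 15.4 CPM against 5.72 CPM, ZSCAN26 at 10.7 CPM against 4.30 CPM and SERF2 at 12.3 CPM against 1.56 CPM. The splicing factor gene SF3A2 (60.3 CPM against 25.04 CPM), the circadian gene PER1 (25.3 CPM against 10.4 CPM) and TXNRD2 (14.5 CPM against 5.86 CPM) were called as measured, but their GC-corrected log2 ratios of 0.93, 0.97 and 0.97 were under the threshold. Among the lowest genes, HBB was at 0.177 CPM against 54.1 CPM, RBM27 at 0.840 CPM against 10.6 CPM, the splicing factor SRSF1 at 2.74 CPM against 20.3 CPM, LYSMD3 at 1.504 CPM against 12.6 CPM, TMED7 at 4.11 CPM against 26.1 CPM and SAMD9 at 8.01 CPM against 47.2 CPM. CALM2 (16.0 CPM against 126.8 CPM) and TPT1 (12.6 CPM against 64.9 CPM) were lower too, with counts made uncertain by pseudogenes.

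Of the lists in deltaCC against TAZ-KO, 7 stood apart. The actin and SRF list had a median log2 ratio of 0.29 (percentile 99.9; 94.1 after GC correction) with 0 of 28 called. Immediate early genes had a median of 0.33 (percentile 99.7), with 2 of 23 higher, NR4A1 at 3.45 CPM against 0.898 CPM among them. Mitochondrially encoded genes had a median of 0.39 with 0 of 13 called (2 higher after GC correction), and histones had 0.59 (percentile 99.8) with 2 of 11 higher, HIST1H1E at 8.89 CPM against 3.45 CPM among them. Ribosomal proteins had a median of -0.082 (percentile 0) with 36 of 52 below 0 and none called. Blood markers had a median of -1.25, with 3 of 6 lower and none higher.

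Flag-TAZ and deltaCC were compared directly, which addresses what the coiled coil changes. Few genes differed: 193 were higher in Flag-TAZ and 220 lower among 14322 tested, and with a minimum of 5 CPM 40 were higher and 16 lower. ANKRD1 was at 265 CPM in Flag-TAZ and 144 CPM in deltaCC (log2 ratio 0.88, interval 0.82 to 0.95), CTGF at 364 CPM and 260.4 CPM (0.48), and GADD45A at 33.8 CPM and 19.0 CPM (0.82). None of the 22 signature members was called, and the signature median was 0.046 (percentile 91.5). WWTR1 itself was at 1015 CPM in Flag-TAZ and 679 CPM in deltaCC, so the amount of transcript also differed. The genes highest in Flag-TAZ were HBB at 22.1 CPM against 0.177 CPM, FST at 39.5 CPM against 15.2 CPM, ADM at 69.5 CPM against 28.97 CPM and TMED7 at 10.6 CPM against 4.11 CPM, along with ALPP, KRTAP2-3, RPL23A and CALM2, which have close copies. The single protein-coding gene called lower with at least 10 CPM in the higher library was ZNF814, at 7.80 CPM against 16.6 CPM (log2 ratio -1.04, and just under the threshold after GC correction).

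Among the lists, 9 stood apart between Flag-TAZ and deltaCC, mostly through small shifts shared by many members. Ribosomal proteins had a median log2 ratio of 0.45 (percentile 100) with 52 of 52 above 0 and 1 called, RPL30 at 91.2 CPM against 42.3 CPM. Nuclear-encoded oxidative phosphorylation had a median of 0.31 (percentile 100) with 41 of 42 above 0 and none called (1 higher after GC correction). DNA replication had a median of 0.13 (percentile 99.8) with 28 of 35 above 0, MYC targets 0.17 with 19 of 28 above 0, the unfolded protein and ATF4 response 0.15 (percentile 99.7), and immediate early genes 0.17 (percentile 99.2) with 1 of 23 lower. Integrins had a median of -0.21 (percentile 0.365) with 14 of 15 below 0 and 1 called lower, and NF-kB and inflammatory cytokines -0.16 (percentile 0.54) with 20 of 26 below 0 and 1 called higher. The interferon response had a median of -0.11 (percentile 1.74; 3.73 after GC correction) with 2 of 35 lower, RSAD2 at 1.53 CPM against 3.71 CPM among them. The log2 ratios in this comparison went down with transcript length (Spearman rho across genes -0.287), and after GC and length correction the ribosomal and oxidative phosphorylation medians were 0.42 and 0.26, with a percentile of 100 for both.

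**Figure D4:**
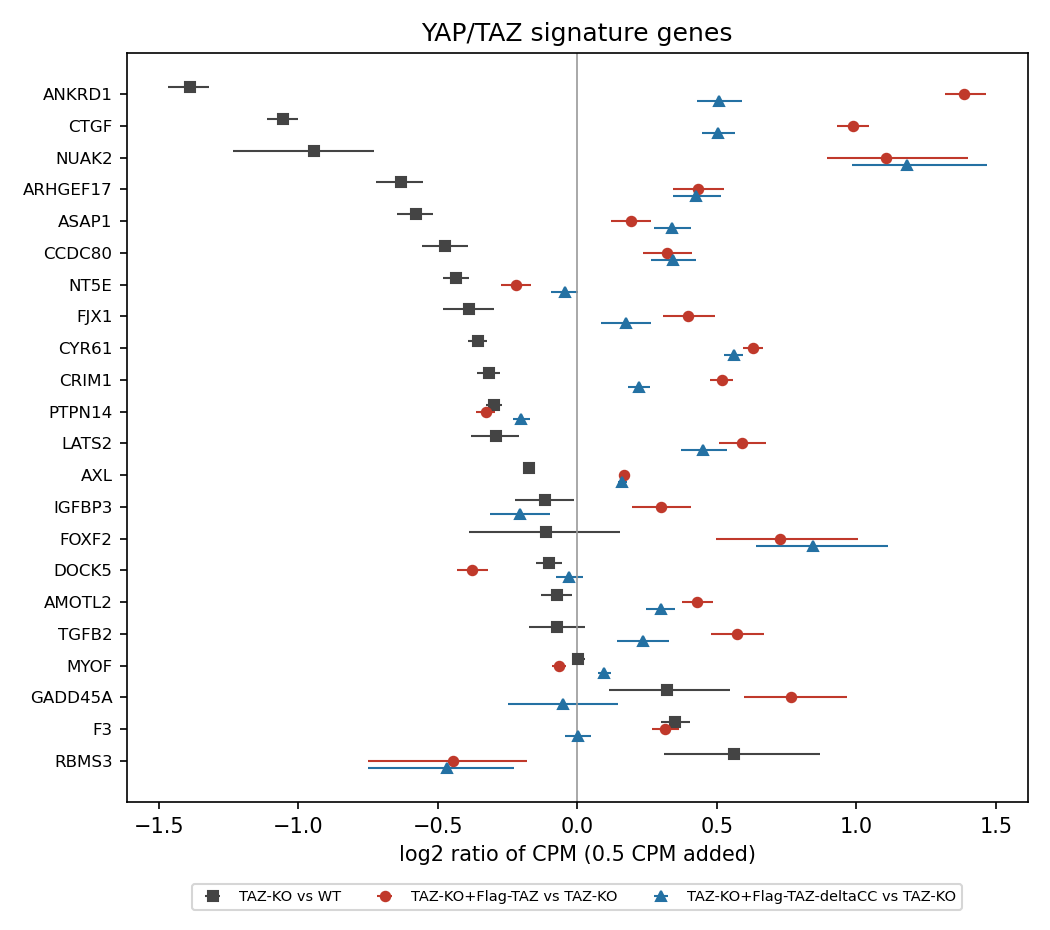
Log2 ratios of the 22 YAP/TAZ signature genes with 95% counting intervals for TAZ-KO against WT (dark grey squares), Flag-TAZ against TAZ-KO (red circles) and deltaCC against TAZ-KO (blue triangles). In TAZ-KO 18 members lie below 0, and 17 and 16 lie above 0 in Flag-TAZ and deltaCC.

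The return of TAZ-dependent transcripts, those lower in TAZ-KO than in WT, addresses whether TAZ needs its coiled coil to restore them. Of 793 such genes, 276 (34.8%) were higher again in Flag-TAZ than in TAZ-KO by the size rule and 284 (35.8%) in deltaCC, with 195 in both. With a minimum of 5 CPM in both steps these were 46 and 41 of 234 genes. The median share of the loss that was recovered was 59.7% in Flag-TAZ (95% bootstrap interval over genes 56.3 to 64.4) and 63.6% in deltaCC (61.0 to 67.3). These intervals resample genes that vary together within the same libraries. They leave out the spread between libraries, so they test neither Flag-TAZ against deltaCC nor either one against simulation. Because the genes are chosen on the TAZ-KO library, libraries simulated without any difference also gave a recovered share, 57.2% in Flag-TAZ and 58.5% in deltaCC at an assumed coefficient of variation of 0.2 (121 genes per simulation), while lower coefficients gave fewer than 5 genes. In the same simulations 17.4% and 18.2% of the genes were called higher again in Flag-TAZ and deltaCC. With a minimum of 5 CPM in WT or TAZ-KO, 25.2% and 20.9% of the genes were restored, against 18.2% in simulation for both, and with a minimum of 10 CPM 19.5% and 11.7%, against 18.5% and 17.8%. Between Flag-TAZ and deltaCC the median log2 ratio of the 793 genes was -0.029 (percentile 45.6), with 18 higher in Flag-TAZ and 23 lower. SPATA5L1 recovered 87.4% of its loss in Flag-TAZ and 88.5% in deltaCC, HAS2 69.6% and 50.5%, CRIP2 46.2% and 22.5%, and KLF9 37.0% and 35.2%. SERPINA1 recovered 12.7% and 11.3%, and THBS2 10.9% and 18.4%. TRPV4 had 0 counts in TAZ-KO and 2 in each of Flag-TAZ and deltaCC, and PAGE2 had 0 counts in both, so no share is given. Of the 930 genes higher in TAZ-KO than in WT, 450 were lower again in Flag-TAZ and 423 in deltaCC, with 301 in both. These genes too are chosen on the TAZ-KO library. Their median share returned was 67.4% in Flag-TAZ and 64.2% in deltaCC. In simulation without any difference it was 41.3% in Flag-TAZ at an assumed coefficient of variation of 0.2 (119 genes per simulation). Their median log2 ratio between Flag-TAZ and deltaCC was -0.048 (percentile 31.2), but 0.069 (percentile 99.3) with a minimum of 5 CPM. In both libraries, 145 of the 930 and 109 of the 793 still had the call they had in TAZ-KO against WT, 254 of 1723 (14.7%).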

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

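All tests in this part were chosen after the results were seen. The interferon response had opposite directions in the knockouts: its median log2 ratio to WT was 0.28 in TAZ-KO and -0.34 in YAP-KO, and the difference was not tested. Ribosomal proteins had opposite directions with the forms of TAZ: their median log2 ratio to TAZ-KO was 0.39 in Flag-TAZ and -0.082 in deltaCC. Flag-TAZ against deltaCC directly gave a median of 0.45, with 52 of 52 above 0, but with 1 library of each form no test of the difference against the spread between replicates was possible.

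In YAP-KO against WT the log2 ratios went down with transcript GC content (Spearman rho across genes -0.622). The same slope ran within lists whose members tend to be regulated together, with rho of -0.713 among 42 oxidative phosphorylation genes and -0.314 among 52 ribosomal proteins, both outside the range of permuted GC values, so GC-dependent recovery in library preparation or sequencing may account for it. The ribosomal list adds little to this. In Flag-TAZ against deltaCC its rho was 0.356, also outside the permuted range, though the rho across genes was 0.0729. The oxidative phosphorylation rho there was 0.137, inside the permuted range. The fitted trend is not the whole source of the calls in YAP-KO, because 1882 of the 4376 called genes had the same call and direction after it was removed. It was fitted on each gene's longest transcript, so GC-dependent recovery that it misses is not excluded for these calls. A change of expression that follows the loss of YAP stays open: Flag-TAZ against TAZ-KO, where YAP1 was not called, had a trend with a rho of 0.495, so such trends also occur without a difference in YAP1, yet with 1 YAP-KO library its trend and its label cannot be told apart.

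Erythroid transcripts were present in WT, TAZ-KO and Flag-TAZ and nearly missing in deltaCC and YAP-KO: HBB had 1145 counts in TAZ-KO, 299 in WT, 377 in Flag-TAZ, 4 in YAP-KO and 4 in deltaCC. Reads from erythroid cells or blood may be the source, since 5 of the 6 erythroid genes besides HBB and HBA1 (a near-copy of HBA2) with at least 10 counts over all libraries were higher in each of these 3 libraries than in both others, among them HBA2 (140 counts in TAZ-KO), SLC4A1 (186) and ALAS2 (88), while SELENBP1 was expressed in every library. Of the 6 white blood cell genes with as many counts 2 were, S100A8 and S100A9 (162 counts in TAZ-KO, 94 in Flag-TAZ, 28 in WT, 24 in deltaCC and 0 in YAP-KO), and CSF3R, FCGR3B, CXCR2 and S100A12 had 0 in every library. Whether a single blood source was mixed in at different amounts stays open: 4 of 5 ratios to HBB (HBA1, HBA2, ALAS2 and HBD) had overlapping counting intervals in the 3 libraries, while SLC4A1 had 5.57 counts per 100 HBB counts in Flag-TAZ (95% interval 3.41 to 8.64) and 22.7 in WT (17.2 to 29.7), and counting error alone gives no spread between libraries. Against the presence or absence of TAZ alone, HBB was 83.9-fold higher in WT than in YAP-KO (32.4 to 309.8), neither of which is labelled as a TAZ knockout.

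Of the 1723 genes called in TAZ-KO against WT, 254 had the same call against WT in both Flag-TAZ and deltaCC. Of these, 37.0% had the same call in YAP-KO against the same WT library. This does not exclude an error of the WT library as the source of all of them. A difference of the YAP-KO library itself, such as its GC trend, can also keep a gene from being called there. Too little WWTR1 mRNA in a library as a whole does not account for the 254 genes, since WWTR1 stood at 5.82-fold its WT level in the lower of the 2 libraries. This count can include the transcript of the knockout gene, which stood at 169 CPM in TAZ-KO. A library mean also does not show whether every cell carried the added form. What stays open is a lasting difference of the TAZ-KO cells that does not follow TAZ. Cells without the added form and a re-expressed protein that works in part stay open too. With 1 TAZ-KO library these cannot be told apart. An error of the WT library stays open as well, for the 94 genes also called in YAP-KO and for the others, because there is 1 WT library.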

How the results depend on the processing

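The GC correction, the GC and length correction, the scaling without the YAP-KO library and the minimum of 5 or 10 CPM in WT or TAZ-KO for the TAZ-dependent genes were chosen after seeing the data, and the other alternatives were fixed beforehand. No paired analysis was possible because each group had 1 library, and for the same reason no library of a group could be left out. For the 18 main results, 178 of 258 values kept their range, and 80 did not: 78 moved and 2 came to stand apart. For called genes this is judged on their total, and the split into higher and lower turned in YAP-KO with upper-quartile factors (1737 and 2827), in deltaCC after GC and length correction (578 and 573), in Flag-TAZ at 4-fold (81 and 72), and in the direct comparison with a minimum of 5 CPM (40 and 16), 2 CPM added (31 and 12), 1.5-fold (737 and 722), 4-fold (6 and 4) and protein-coding genes alone (116 and 78). The signature medians kept their direction and their side of the percentile limits in all 5 comparisons under every alternative run. Where an alternative changes the genes tested (a filter, protein-coding genes alone), the threshold or the added amount, its construction shows why a count moved, and elsewhere the cause was not tested.

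Counts are of genes called, and with the deposited FPKM the counting interval was not part of the call. With upper-quartile factors the share recovered in deltaCC was 68.1%. Without a filter, TAZ-KO had 2889 called genes, Flag-TAZ 2726, deltaCC 2328 and the direct comparison 705, with 483 and 549 genes restored in Flag-TAZ and deltaCC, a share of 55.4% in Flag-TAZ, and 327 genes lower in both knockouts. A minimum of 5 CPM gave 488, 483, 446 and 56, with 46 and 41 restored, shares of 50.8% and 51.3%, and 51 genes lower and 128 higher in both knockouts. Adding 2 CPM gave 438, 412, 352 and 43, with 35 and 26 restored, shares of 49.4% and 49.4%, and 38 lower and 88 higher in both. Adding 0.1 CPM gave 738 in the direct comparison, shares of 65.4% and 68.0%, and 343 lower in both. The deposited FPKM plus 1 gave 546 in TAZ-KO, 2647 in YAP-KO, 565 in Flag-TAZ, 508 in deltaCC and 102 in the direct comparison, with 47 and 45 restored, shares of 52.0% and 57.0%, 53 lower and 70 higher in both, and a median of -0.067 for Flag-TAZ over deltaCC among TAZ-dependent genes (percentile 0.01). A threshold of 1.5-fold gave 3850, 7879, 4051, 3642 and 1459 in the same order, with 726 and 752 restored, shares of 54.0% and 58.0%, 682 lower and 864 higher in both, and a median of -0.031 (percentile 0.99). A threshold of 4-fold gave 189, 720, 153, 102 and 10, with 22 and 19 restored, and 9 lower and 31 higher in both. Protein-coding genes alone gave 1038 in TAZ-KO, 955 in Flag-TAZ, 882 in deltaCC and 194 in the direct comparison, with 179 restored in deltaCC and 117 lower in both. GC correction gave 2542 in YAP-KO and 171 higher in both, and GC and length correction 2204 and 160. A minimum of 10 CPM in WT or TAZ-KO left 25 and 15 restored, with shares of 46.6% and 45.2%.

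Some results reversed. Among genes higher in TAZ-KO, the median of Flag-TAZ over deltaCC was 0.069 with a minimum of 5 CPM, 0.0055 at 1.5-fold and 0.14 with a minimum of 10 CPM. TGF-beta targets in Flag-TAZ were at -0.021 after GC and length correction, and ribosomal proteins in YAP-KO at -0.054 with upper-quartile factors, where all YAP-KO ratios shift. In YAP-KO against WT, heat shock genes were at -0.0031 after GC correction and -0.12 after GC and length correction, RBMS3 at -0.12 and MOB1B at -0.24 after GC correction, DNAJB4 at -0.19 and -0.30, and RPL5 at -0.092 and -0.39. Of the values for other medians, 449 stayed the same, 34 weakened and 7 reversed. Lists that stopped standing apart under the deposited FPKM plus 1 were epithelial and endothelial markers, collagens, metastasis genes and immediate early genes in TAZ-KO, collagens and the EGFR family in YAP-KO, integrins and luminal markers in Flag-TAZ, and the interferon response in the direct comparison. Immediate early genes in TAZ-KO and luminal markers in Flag-TAZ also did so with FPKM plus 0.1 and with 2 CPM added, and metastasis genes in TAZ-KO with 2 CPM added. Cholesterol synthesis in TAZ-KO, collagens, heat shock genes and blood markers in YAP-KO, immediate early genes and TGF-beta targets in Flag-TAZ and actin and SRF genes in deltaCC did so after GC correction and after GC and length correction. The interferon response in the direct comparison did so after GC correction, and the EGFR family in YAP-KO and replication genes and MYC targets in Flag-TAZ after GC and length correction. Blood markers also did so in YAP-KO with median-of-ratios and upper-quartile factors and with 2 CPM added, and in Flag-TAZ with 0.1 CPM added.

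GC correction also brought lists to stand apart that did not as measured. These were Hippo components, antigen presentation and heat shock genes in TAZ-KO; Hippo components, integrins, immediate early genes, MYC targets and luminal markers in YAP-KO; and Hippo components, mitotic genes, antigen presentation, the unfolded protein response, oxidative phosphorylation and mitochondrially encoded genes in Flag-TAZ. Cholesterol synthesis and oxidative phosphorylation did so in deltaCC, and mitotic genes and collagens in the direct comparison. Of 403 values for single genes, 171 kept their call under every alternative. Depth limits the low genes: 3 counts correspond to 0.133 to 0.176 CPM, and 34 of 165 list medians include a member at 0 counts, which moves a median by at most 0.171 when set to the floor.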

Other observations

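Values for other comparisons of the fixed lists follow, with GC-corrected values in brackets for YAP-KO. Hippo pathway components did not stand apart in TAZ-KO against WT (median log2 ratio -0.095, percentile 22.5) but did after GC correction (-0.23, percentile 0.04), and the LIM protein AJUBA, which binds LATS kinases, was at 279.6 CPM against 581 CPM, with the other 24 not called. In YAP-KO against WT the Hippo components had a median of -0.50 (percentile 3.53; -0.58 and percentile 0.15 after GC correction), with 6 of 25 lower and 1 higher (6 and 0 after GC correction): the atypical cadherin FAT1 was at 1237 CPM against 3160.1 CPM and the scaffold WWC1 at 32.1 CPM against 80.2 CPM. Mesenchymal markers did not stand apart in YAP-KO (median 0.050, percentile 80.6; -0.055 and percentile 74.0 after GC correction), yet fibronectin (FN1) was at 489 CPM against 1016 CPM and the cadherin CDH11 at 178 CPM against 386 CPM, and 4 of 15 were lower and none higher (5 and 1 after GC correction). Among class II and other antigen-presentation genes in YAP-KO (median -0.17, percentile 38.7; -0.057 and percentile 61.5 after GC correction; 0.28 and percentile 98.4 after GC and length correction), 6 of 19 were higher and 3 lower (8 and 3 after GC correction): HLA-DPA1 was at 64.2 CPM against 18.1 CPM and HLA-DRB1 at 32.1 CPM against 8.83 CPM, while TAPBP, the chaperone tapasin, was at 190.5 CPM against 659 CPM. NF-kB and inflammatory cytokines in YAP-KO had a median of 0.044 (percentile 73.0; -0.037 with members at 0 counts set to the floor; -0.18 and percentile 28.6 after GC correction), with 7 of 26 higher and 4 lower (3 and 4 after GC correction), and CSF1, the macrophage growth factor, was at 192 CPM against 620.4 CPM and TNF at 0.536 CPM against 4.61 CPM. TNF was lower in TAZ-KO as well, at 0.425 CPM, in a list with a median of 0.0087 (percentile 69.8).

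Luminal breast markers had a median of -0.68 in YAP-KO (percentile 3.26; -0.51 with members at 0 counts set to the floor; -0.77 and percentile 0.54 after GC correction), with 4 of 10 lower, SPDEF at 29.9 CPM against 134 CPM among them. The p53 targets in YAP-KO (median -0.0084, percentile 27.5; 0.17 and percentile 73.7 after GC correction) went both ways, with PHLDA3 at 2.64 CPM against 15.8 CPM and FAS at 7.55 CPM against 1.30 CPM. Cholesterol synthesis in YAP-KO (median -0.21, percentile 6.88; -0.16 and percentile 11.6 after GC correction) had 5 of 24 higher and 5 lower (2 and 2 after GC correction), with CYP51A1 at 0.805 CPM against 6.82 CPM and IDI1 at 57.6 CPM against 14.5 CPM. The unfolded protein and ATF4 response in YAP-KO had a median of 0.24 (percentile 94.1; 96.8 after GC correction and 98.04 after GC and length correction), with 5 of 26 higher and none lower (2 and 0 after GC correction), ATF4 at 311 CPM against 109 CPM among them. TGF-beta and SMAD targets in TAZ-KO (median -0.046, percentile 46.3) had 2 of 20 higher and 2 lower: INHBA was at 13.6 CPM against 3.56 CPM and BMP4 at 58.5 CPM against 151 CPM. In YAP-KO AP-1 factors had a median of -0.41 (percentile 21.4), but 0.015 (percentile 78.5) after GC correction. Hypoxia and glycolysis did not stand apart in YAP-KO (median -0.078, percentile 62.6; -0.022 and 78.1 after GC correction), nor did basal mammary markers (-0.014, percentile 38.9; 0.33 and 78.4 after GC correction) or markers of HEK293 cells (-0.15, percentile 22.1, with 4 measured; 0.16 and 52.9 after GC correction). Among white blood cell genes, PTPRC had between 2 and 14 counts, LYZ between 3 and 56 and S100A9 between 0 in YAP-KO and 162 in TAZ-KO.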
